A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

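PolyA RNA was sequenced from Schizosaccharomyces pombe WT and the mutants ubp8 and ubp16, untreated or after 30 min with 1 mM hydrogen peroxide, in 2 libraries for each of 6 groups. Groups were taken from the sample labels. The labels do not say whether the 2 libraries of a group came from separate cultures, so each p-value measures the spread between these samples only. The deposited values are raw counts of reads per gene, 1 column for each of the 12 libraries. The submitters' processing notes name FastQC, Trimmomatic, STAR, HTSeq and DESeq2 without versions. The genome build is not given in the sources used here. The ASM294v3 reference served for names, biotypes, lengths and neighbouring genes, and no coordinates were taken from the authors' files. Of 12683 genes listed, 12602 matched this reference by identifier, and the 81 others held 0.064% of all counts.

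Total counts per library ran from 9904056 to 14054746. At the lowest total, 3 counts came to 0.293 CPM after scaling. This floor covers counting error only. Pearson correlations of log2 CPM between the libraries of a group ran from 0.9887 to 0.9918, across genes that are not independent replicates. Reads were assigned by strand as far as could be tested: 92.1% of 825 coding genes with at least 95% of exon length opposite another exon had a mean of at least 10 counts, against 89.6% of 518 with nothing opposite.

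Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr, which left 8166 genes (4954 coding, 3109 long non-coding, 42 small nucleolar, 22 pseudogenes) that held 99.95% of counts. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, with 6 residual degrees of freedom. The 11 comparisons were the response to peroxide in each strain, each mutant against WT and ubp16 against ubp8 in each condition, and the interaction of each mutant with treatment. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. SE are the log2 fold change divided by the square root of the quasi-likelihood F. Gene lists were tested with camera, which compares a list with all other tested genes, at a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the data. With an estimated correlation 4 of 109 list calls held: Pap1 targets, antioxidant enzymes and ribosome biogenesis in the ubp16 response, and mating and nitrogen starvation genes in untreated ubp16 against WT. Of the calls for classes of RNA, those given with an estimated adjusted p under 0.05 held.

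The lists were written from general knowledge before the data were examined: core stress genes, Pap1 targets, antioxidant enzymes, chaperones, proteasome and polyubiquitin, cytosolic ribosomal proteins, ribosome biogenesis, respiratory chain, glycolysis, glucose-repressed genes and hexose transporters, sulfur assimilation, iron uptake, phosphate acquisition, core histones, H2B ubiquitination and COMPASS, SAGA, ubiquitin-specific proteases, mating and nitrogen starvation, meiotic genes, MBF cell cycle genes, cell separation genes, Tf2 retrotransposons and subtelomeric helicases, strain background markers, and markers of P cells and of M cells. A list of 7 mitochondrially encoded genes matched no gene of the table and was not tested. Lists with under 3 tested members had no set test. Histone, ribosomal protein, Tf2 and helicase genes have near-identical copies, among which reads cannot be placed with certainty.

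The rule for named genes was also fixed before the data were examined. It took ubp8, ubp16 and ctt1, and for each comparison up to 8 coding genes per direction with the largest fold changes, a mean of at least 50 counts and, outside the interactions, no overlap between the libraries of both groups. It further took from each list up to 4 called members with the largest fold changes and up to 2 others, and the called members of the marker and protease lists in comparisons of strains. Each comparison names a part of this set. The responses of urg1 in ubp16 and of urg1 and urg2 in ubp8, the small nucleolar RNAs named singly and the library shares of RNA classes were chosen after the values were seen. Genes with a group at or near the floor were left out.

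Sets of peroxide-responsive genes were those called at 2-fold or more in the mutant that a contrast leaves out, so that the set and the contrast share no mutant library. Overlaps of called genes were compared with the product of the list sizes over 8166, and with 20 simulations of data with no effect in which contrasts share WT libraries. The alternatives tried were median-of-ratios factors, library totals, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 50 counts, coding genes outside multi-copy families, only the libraries of a comparison, a replicate block, a 2-fold threshold, a 4-fold threshold for the response sets, the 20 core stress genes in their place, and each library left out in turn. List tests in a fit of coding genes outside multi-copy families, the overlap of the mutants with library totals, and fits of coding genes and of genes with a mean of at least 50 counts under the scaling of all genes, and lists without ubp8 and ubp16 were added after seeing the data.

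The model was tested on simulated data of 8166 genes with 50 changed at each fold. In untreated ubp8 against WT it recovered 42% of genes changed 1.5-fold, 62% at 2-fold, 80% at 3-fold and 88% at 4-fold, and called 11 of 7966 unchanged genes. For the ubp8 interaction the shares were 20%, 52%, 66% and 74%, with 6 of 7966 called.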

Results

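PolyA RNA was measured by RNA-seq in fission yeast (Schizosaccharomyces pombe) of 3 strains: wild type (WT) and the mutants ubp8 and ubp16, each named after the ubiquitin-specific protease gene it affects. Ubp8 is the deubiquitinating enzyme of the SAGA coactivator complex. Each strain was sampled untreated and after 30 min in 1 mM hydrogen peroxide, with 2 libraries in each of the 6 groups. The first principal component held 46.0% of the variance and parted treated from untreated libraries, and the second held 24.4%. The 2 libraries of a group lay close together in each of the 6 groups. Fold changes below are log2 values ± SE from 2 libraries per group, levels are library-scaled counts (CPM), and genes were called at an adjusted p under 0.05. Gene lists fixed before the counts were seen were tested with camera, which sets a list against all other genes.

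**Figure D1:**
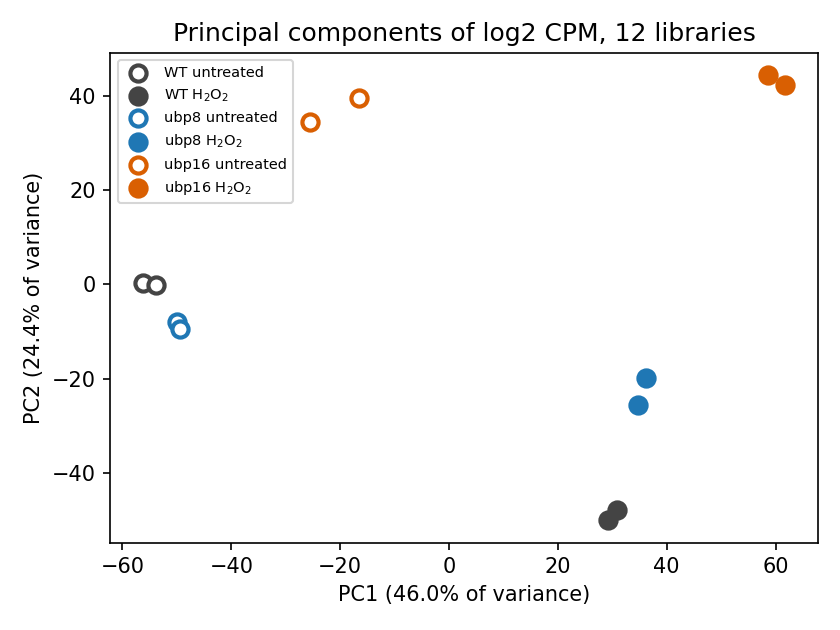
First and second principal components of log2 CPM, with open points for untreated and filled points for treated libraries. The first component, with 46.0% of the variance, separates the treated libraries from the untreated ones.

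The mutated genes were measured first, together with ctt1, which encodes catalase and is a classical readout of the peroxide response. In the ubp8 mutant the ubp8 transcript (SPAC13A11.04c) stood at 26.2% of the WT level untreated (-1.93 ± 0.14) and 29.6% treated (-1.76 ± 0.15), lower in both libraries each time. In the ubp16 mutant the ubp16 transcript (SPCC1682.12c) stood at 46.5% and 48.4% of WT (-1.10 ± 0.15 and -1.05 ± 0.17). Neither transcript was at 0, and the labels do not state how the genes were changed. Of the annotated exon length, 25.3% of ubp8 and 41.1% of ubp16 lies outside the coding sequence, and counts per gene do not show where in a gene the reads fall. In the 2 untreated libraries ubp8 had 33.89 and 34.08 CPM in WT against 9.493 and 8.34 in the ubp8 mutant. For ubp16 the untreated levels were 46.68 and 54.3 CPM in WT against 22.16 and 24.95 in the ubp16 mutant. Peroxide lowered the ubp16 transcript in WT (-1.13 ± 0.15). Untreated ubp8 cells also held less ubp16 transcript than WT (-0.65 ± 0.14). This difference did not pass with library totals as scaling (-0.36, adjusted p = 0.0637) or without replicate 2 of untreated WT (-0.47).

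Catalase transcript rose with peroxide in all 3 strains: ctt1 (SPCC757.07c) changed by 4.32 ± 0.26 in WT, 4.61 ± 0.26 in ubp8 and 3.75 ± 0.25 in ubp16. Before treatment it was already higher than in WT in ubp8 (0.79 ± 0.23, adjusted p = 0.0142) and in ubp16 (2.71 ± 0.24, adjusted p = 4.17e-07). The untreated ubp8 difference did not pass without replicate 1 of untreated WT (0.56) or replicate 2 of untreated ubp8 (0.69). After treatment ctt1 stood at 210.1% of the WT level in ubp8 (1.07 ± 0.23) and 438.1% in ubp16 (2.13 ± 0.23). Its response in ubp8 (0.28 ± 0.32, adjusted p = 0.582 for the difference from WT) and in ubp16 (-0.57 ± 0.32, adjusted p = 0.203) was not called different in size. The ubp16 value passed without replicate 1 of untreated ubp16 (-0.96) and with no count filter (-0.57, adjusted p = 0.00318). Untreated ubp16 libraries differed from each other in ctt1, at 640.7 and 1212 CPM.

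**Figure D2:**
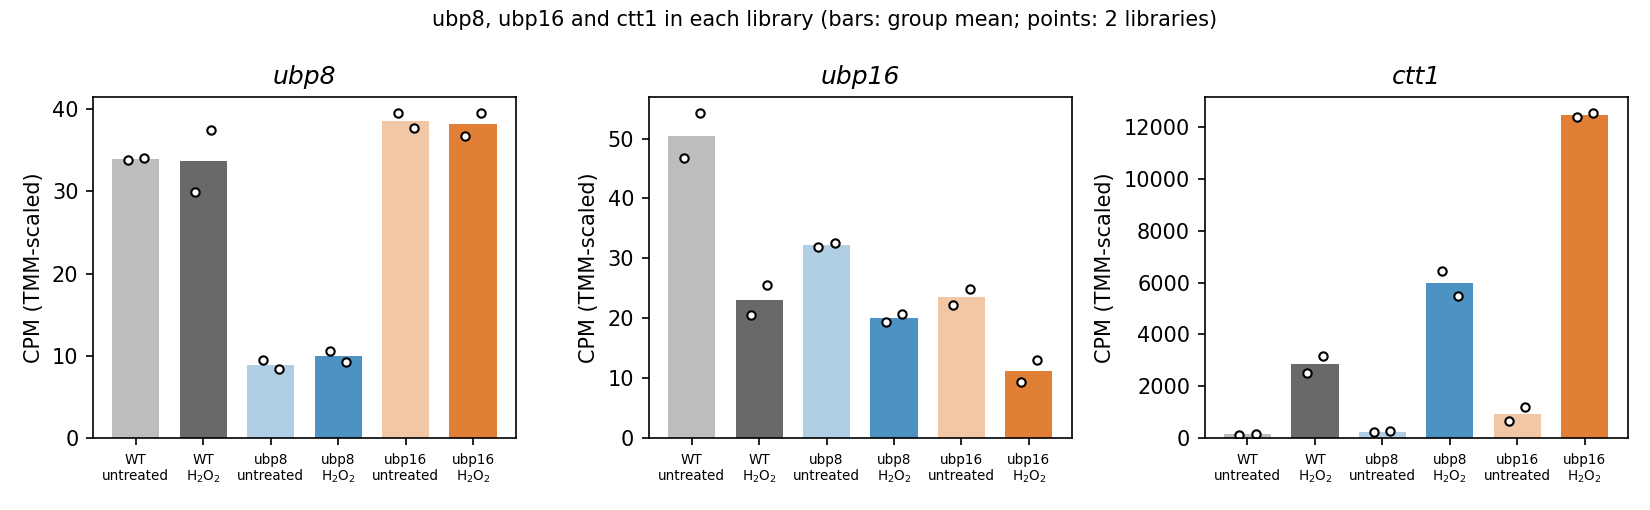
CPM of ubp8, ubp16 and ctt1 in each library, with bars for group means and points for the 2 libraries. In the mutants ubp8 stood at 26.2% and ubp16 at 46.5% of the untreated WT level.

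The first comparison asked what 30 min of peroxide did to WT. Large rises were in ddr48 (8.38 ± 0.39), wwm3 (7.77 ± 0.33), ssd2 (7.47 ± 0.37), lsd90 (7.41 ± 0.37) and hsp3101 (5.89 ± 0.26). Large falls were in pho842 (-5.55 ± 0.19), urg1 (-4.68 ± 0.26), urg2 (-4.08 ± 0.21), eng1 (-4.67 ± 0.21), gas1 (-4.43 ± 0.20) and cts2 (-3.97 ± 0.22). Here pho842 encodes a phosphate transporter, eng1 the glucanase that dissolves the septum, and cts2 a chitinase.

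Core stress genes are targets of the kinase Sty1 and the factor Atf1: of 20 members tested, 16 rose and 4 did not pass (16 higher adjusted over the list alone). The median was 3.51 (adjusted p = 1.32e-17, and adjusted p = 0.161 with an estimated correlation). Examples were lsd90 (7.41 ± 0.37), ish1 (5.51 ± 0.24) and pyp2 (5.09 ± 0.22), while fbp1 stood at 0.37 ± 0.31, adjusted p = 0.345. Pap1 is the oxidant-sensing AP-1-like factor, and of 12 Pap1 targets tested, 9 rose, 1 fell and 2 did not pass (9 higher and 2 lower adjusted over the list alone). Their median was 1.16 (adjusted p = 3.01e-06, and adjusted p = 0.183 with an estimated correlation). The sulfiredoxin gene srx1 rose by 4.88 ± 0.13 and gst3 by 3.79 ± 0.16. Of 21 antioxidant enzymes tested, 19 rose, 1 fell and 1 did not pass (20 higher and 1 lower adjusted over the list alone), with gpx1 (3.51 ± 0.23) and grx1 (2.28 ± 0.16) among those that rose. The median was 0.73 (adjusted p = 1.76e-08, and adjusted p = 0.161 with an estimated correlation). The fall of trx2 (-0.33 ± 0.11) was not called without replicate 1 of untreated WT (-0.27) or replicate 1 of treated WT (-0.21). It stood at -0.53 with library totals. Chaperone genes moved as a group: of 16 members tested, 15 rose and 1 fell (15 higher and 1 lower adjusted over the list alone), led by ssa1 (5.47 ± 0.25), hsp104 (4.82 ± 0.22) and hsp16 (4.54 ± 0.29). Their median was 1.23 (adjusted p = 1.9e-10, and adjusted p = 0.179 with an estimated correlation). Of 17 proteasome and polyubiquitin genes tested, 16 rose and 1 did not pass (17 higher adjusted over the list alone), with ubi4, which encodes polyubiquitin, at 2.01 ± 0.15. The median was 0.67 (adjusted p = 6.35e-06, and adjusted p = 0.405 with an estimated correlation).

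Of 57 ribosome biogenesis genes tested, 51 fell and 6 did not pass (53 lower adjusted over the list alone), with mpp10 (-1.96 ± 0.09), nop4 (-1.92 ± 0.09), nop52 (-1.90 ± 0.14) and imp4 (-1.89 ± 0.10). Their median was -0.89 (adjusted p = 1.09e-20, and adjusted p = 0.161 with an estimated correlation). The list of cytosolic ribosomal proteins was not called: of 139 members tested, 1 rose, 28 fell and 110 did not pass (1 higher and 19 lower adjusted over the list alone, median -0.14, adjusted p = 0.08). Of 10 cell separation genes tested, 10 fell (10 lower adjusted over the list alone), with adg1 at -3.50 ± 0.20. The median was -3.08 (adjusted p = 1.45e-12, and adjusted p = 0.161 with an estimated correlation). Of 9 MBF cell cycle genes tested, 1 rose, 7 fell and 1 did not pass (2 higher and 7 lower adjusted over the list alone), where mik1 (-2.76 ± 0.25) and cig2 (-2.41 ± 0.13) fell and cdt2 (0.70 ± 0.14) rose. Their median was -1.37 (adjusted p = 0.00116, and adjusted p = 0.588 with an estimated correlation). Of 16 mating and nitrogen starvation genes tested, 3 rose, 10 fell and 3 did not pass (3 higher and 10 lower adjusted over the list alone): ste11, the master factor of mating, fell (-3.95 ± 0.28) and inv1, which encodes invertase, rose (4.99 ± 0.18). The median was -1.07 (adjusted p = 0.403). Of 3 P-cell mating-type markers tested, 3 fell (3 lower adjusted over the list alone). Their median was -1.26 (adjusted p = 0.356). Of 5 M-cell markers tested, 2 fell and 3 did not pass (2 lower adjusted over the list alone). The median was -0.61 (adjusted p = 0.444). Of 15 ubiquitin-specific proteases tested, 5 rose, 4 fell and 6 did not pass, with ubp11 at 2.57 ± 0.13 and ubp15 at 1.59 ± 0.11 (5 higher and 4 lower adjusted over the list alone, median -0.04, mean 0.18, adjusted p = 0.444). Of 6 meiotic genes tested, 3 rose, 1 fell and 2 did not pass (3 higher and 1 lower adjusted over the list alone), with rec8 at 1.65 ± 0.26. Their median was 0.63 (adjusted p = 0.492). Of the 2 phosphate acquisition genes tested, pho4 fell (-1.39 ± 0.12, 1 adjusted over the list alone).

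Of 8166 genes tested in WT, 2139 genes were higher and 2207 lower, of which 1077 and 865 by at least 2-fold. The split depended on scaling: scaled by library totals alone, the split was 1686 higher and 2948 lower, with the median of all genes shifted by -0.191. Small nucleolar RNAs rose as a class in treated WT, with a median of 0.871 over 42 genes and 22 called higher (adjusted p = 0.0012, and adjusted p = 0.246 with an estimated correlation).

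The second comparison asked the same of the ubp8 mutant. Genes with large rises were ssd2 (7.68 ± 0.36), ddr48 (7.26 ± 0.36), lsd90 (6.48 ± 0.35), wwm3 (6.23 ± 0.30) and smp4 (6.03 ± 0.33). Large falls were in cts2 (-5.01 ± 0.23), gas1 (-4.50 ± 0.20), eng1 (-4.44 ± 0.21) and pho842 (-4.40 ± 0.17). Of 20 core stress genes tested, 18 rose, 1 fell and 1 did not pass (18 higher and 1 lower adjusted over the list alone). The median was 2.95 (adjusted p = 9.64e-19, and adjusted p = 0.127 with an estimated correlation). Of 12 Pap1 targets tested, 11 rose and 1 fell (11 higher and 1 lower adjusted over the list alone): srx1 (4.99 ± 0.12), gst3 (4.18 ± 0.16) and gst2 (3.61 ± 0.18) rose and sro1 (-0.53 ± 0.14) fell. Their median was 2.42 (adjusted p = 4.97e-16, and adjusted p = 0.0575 with an estimated correlation). The fall of sro1 was -0.84 without replicate 2 of treated ubp8 and -0.86 with library totals. Of 21 antioxidant enzymes tested, 19 rose, 1 fell and 1 did not pass (20 higher and 1 lower adjusted over the list alone), with trr1, which encodes thioredoxin reductase, at 2.53 ± 0.17. The median was 1.02 (adjusted p = 2.14e-13, and adjusted p = 0.0575 with an estimated correlation).

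Chaperones rose in part in treated ubp8 cells: of 16 members tested, 10 rose, 1 fell and 5 did not pass (10 higher and 1 lower adjusted over the list alone), with ssa1 at 4.71 ± 0.24. Their median was 0.76 (adjusted p = 8.01e-06, and adjusted p = 0.381 with an estimated correlation). Proteasome and polyubiquitin genes went up together: of 17 members tested, 17 rose (17 higher adjusted over the list alone), with rpt6 at 1.38 ± 0.11. The median was 0.77 (adjusted p = 1.46e-07, and adjusted p = 0.313 with an estimated correlation). Of 57 ribosome biogenesis genes tested, 53 fell and 4 did not pass (53 lower adjusted over the list alone), with nop2 at -1.83 ± 0.09. Their median was -1.04 (adjusted p = 3.49e-29, and adjusted p = 0.0575 with an estimated correlation). Of 139 cytosolic ribosomal proteins tested, 1 rose, 38 fell and 100 did not pass (1 higher and 29 lower adjusted over the list alone). The median was -0.17 (adjusted p = 0.00981, and adjusted p = 0.826 with an estimated correlation). The list of ribosomal proteins was not called without replicate 1 of untreated ubp8 (median -0.09). Its median was -0.27 without replicate 1 of treated ubp8 or in a fit of coding genes alone, -0.26 with no count filter and -0.49 with library totals. Of 10 cell separation genes tested, 10 fell (10 lower adjusted over the list alone). Their median was -2.70 (adjusted p = 2.32e-13, and adjusted p = 0.127 with an estimated correlation). Of 9 iron uptake genes tested, 7 rose and 2 did not pass (7 higher adjusted over the list alone), among them sib2 (3.05 ± 0.13) and frp1 (2.10 ± 0.21). The median was 0.57 (adjusted p = 0.00981, and adjusted p = 0.487 with an estimated correlation). Against coding genes alone the iron uptake list was not called (0.46, adjusted p = 0.0951). With library totals the medians were 0.44 for chaperones, 0.45 for proteasome and polyubiquitin genes and 0.24 for iron uptake genes.

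In treated against untreated ubp8 cells, 2290 genes were higher and 2105 lower, of which 859 and 967 by at least 2-fold. With scaling by library totals alone the split was 1425 higher and 3483 lower, with the median of all genes shifted by -0.323. In a fit of coding genes alone the median of the coding genes shifted by -0.102. The response was compared with that of WT, with which it shares no library: 1610 genes were called higher in both, where independent lists of those sizes would share 599.8, and 1431 lower in both, where 568.9 would be shared. Across genes, which are not independent replicates, the responses of both strains had a Pearson correlation of 0.728. Opposite calls were made for 82 genes.

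The third comparison asked the same of the ubp16 mutant. Large rises were in shu1 (6.28 ± 0.41), ssa1 (5.90 ± 0.25), osr1 (5.76 ± 0.19), srx1 (5.71 ± 0.12) and adh8 (5.56 ± 0.17), of which shu1 serves heme uptake and ssa1 is a heat shock chaperone. Large falls were in adg1 (-5.47 ± 0.27), cts2 (-5.46 ± 0.24) and eng1 (-4.30 ± 0.21), and in hem3, a gene of heme synthesis (-3.90 ± 0.17), and pcl1, which encodes an iron transporter (-3.86 ± 0.17). Of 12 Pap1 targets tested, 12 rose (12 higher adjusted over the list alone): srx1 (5.71 ± 0.12), caf5 (4.89 ± 0.20), trr1 (4.68 ± 0.19) and tpx1 (4.22 ± 0.17), of which tpx1 encodes a peroxiredoxin. Their median was 3.87 (adjusted p = 1.89e-32, and adjusted p = 0.0213 with an estimated correlation). Among 21 antioxidant enzymes tested, 18 rose, 1 fell and 2 did not pass (18 higher and 1 lower adjusted over the list alone), and grx5 was the 1 that fell (-0.61 ± 0.13). The median was 1.22 (adjusted p = 3.13e-16, and adjusted p = 0.0249 with an estimated correlation). Of 20 core stress genes tested, 16 rose, 1 fell and 3 did not pass (16 higher and 1 lower adjusted over the list alone): ctt1 (3.75 ± 0.25), pyp2 (2.94 ± 0.21) and ish1 (2.87 ± 0.21) rose and fbp1 (-1.10 ± 0.16) fell. Their median was 1.78 (adjusted p = 3.84e-08, and adjusted p = 0.3 with an estimated correlation).

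Ribosome biogenesis genes all fell in treated ubp16 cells: of 57 members tested, 57 fell (57 lower adjusted over the list alone), with nop2 (-2.01 ± 0.09), nop14 (-1.95 ± 0.09) and has1 (-1.95 ± 0.10). The median was -1.32 (adjusted p = 3.6e-44, and adjusted p = 0.0249 with an estimated correlation). Of 139 cytosolic ribosomal proteins tested, 1 rose, 99 fell and 39 did not pass (1 higher and 102 lower adjusted over the list alone), with rpl3402 at -1.15 ± 0.10. Their median was -0.46 (adjusted p = 4.44e-07, and adjusted p = 0.777 with an estimated correlation). Iron uptake genes all rose: of 9 members tested, 9 rose (9 higher adjusted over the list alone), with sib2 (3.30 ± 0.14), str3 (2.75 ± 0.33) and frp1 (2.26 ± 0.21). The median was 1.71 (adjusted p = 2.9e-06, and adjusted p = 0.196 with an estimated correlation). Among 10 cell separation genes tested, 10 fell (10 lower adjusted over the list alone). Their median was -3.14 (adjusted p = 3e-16, and adjusted p = 0.107 with an estimated correlation). With library totals the median of ribosomal proteins was -0.70. The protease gene ubp11, which rose in WT, fell here (-1.61 ± 0.16).

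In treated against untreated ubp16 cells, 2055 genes were higher and 2056 lower, of which 917 and 790 by at least 2-fold. With scaling by library totals alone the split was 1394 higher and 3040 lower, with the median of all genes shifted by -0.252. Against the response of WT, 1356 genes were called higher in both, where independent lists of those sizes would share 538.3, and 1341 lower in both, where 555.7 would be shared. The Pearson correlation of both responses across genes, which are not independent replicates, was 0.546, and 208 genes were called in opposite directions.

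The next question was how untreated ubp8 cells differed from untreated WT. Long non-coding RNAs were higher as a class, with a median of 0.679 over 3109 genes (adjusted p = 4.8e-39, and adjusted p = 0.000867 with an estimated correlation). Of these, 896 were called higher and 34 lower, and their share of all counts was 2.4747% and 2.7906% in the 2 ubp8 libraries against 1.772% and 1.639% in WT. Among coding genes large rises were in eno102 (4.14 ± 0.27), cmt2 (3.04 ± 0.21), spn5 (2.56 ± 0.25), aes1 (2.12 ± 0.23), nrg1 (2.10 ± 0.17) and mug14 (2.01 ± 0.17). Marked falls were in msa1 (-2.69 ± 0.19), urg1 (-1.35 ± 0.22), uck2 (-1.29 ± 0.12), pfl3 (-1.22 ± 0.14) and urg2 (-1.11 ± 0.18), besides ubp8 itself; urg1, urg2 and uck2 act in uracil metabolism. Without replicate 2 of untreated WT, urg1 stood at -0.84 and urg2 at -0.72.

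Coding genes as a whole had a median of -0.206 in untreated ubp8 cells, a value that depends on the scaling. Each list was set against all other genes, of which 3109 were long non-coding RNAs with the median of 0.679, so a list can be called lower for this reason alone. Among 139 cytosolic ribosomal proteins tested, 102 were lower and 37 did not pass (111 lower adjusted over the list alone), with rps1002 at -0.85 ± 0.11. The median was -0.40 (adjusted p = 3.28e-18, and adjusted p = 0.428 with an estimated correlation). Of 30 respiratory chain genes tested, 26 were lower and 4 did not pass (27 lower adjusted over the list alone), with rip1 at -0.82 ± 0.11. Their median was -0.48 (adjusted p = 5.05e-12, and adjusted p = 0.428 with an estimated correlation). Among 57 ribosome biogenesis genes tested, 44 were lower and 13 did not pass (46 lower adjusted over the list alone). The median was -0.41 (adjusted p = 1.74e-13, and adjusted p = 0.428 with an estimated correlation). Of 12 glycolysis genes tested, 9 were lower and 3 did not pass (10 lower adjusted over the list alone), with eno101 at -0.57 ± 0.11. Their median was -0.42 (adjusted p = 0.000625, and adjusted p = 0.428 with an estimated correlation). Of 19 SAGA subunit genes tested, 10 were lower and 9 did not pass (11 lower adjusted over the list alone), with ngg1 at -0.48 ± 0.09 (-0.19, adjusted p = 0.0984, with library totals as scaling). The median was -0.32 (adjusted p = 0.00101, and adjusted p = 0.428 with an estimated correlation). Of 15 ubiquitin-specific proteases tested, 7 were lower and 8 did not pass (8 lower adjusted over the list alone). Their median was -0.23 (adjusted p = 0.00101, and adjusted p = 0.428 with an estimated correlation), and it turned to 0.06 with library totals as scaling. Core histone genes stood at a median of -0.30: of 10 members tested, 4 were lower and 6 did not pass (4 lower adjusted over the list alone, adjusted p = 0.0134, and adjusted p = 0.53 with an estimated correlation). This call was lost without replicate 2 of untreated WT (median -0.12). Of 13 H2B ubiquitination and COMPASS genes tested, 1 was higher, 4 were lower and 8 did not pass (1 higher and 5 lower adjusted over the list alone). The median was -0.22 (adjusted p = 0.16), and it turned to 0.07 with library totals.

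The SAGA and protease lists include ubp8 itself. Without ubp8 and ubp16, left out after the values were seen, 9 of 18 SAGA genes were lower (median -0.32, adjusted p = 0.0142) and 5 of 13 proteases (median -0.21, adjusted p = 0.0357). A test of the lists above against coding genes alone was added after the values were seen. It did not call SAGA subunit genes (-0.12, adjusted p = 0.0873), ubiquitin-specific proteases (-0.03, adjusted p = 0.0723) or core histones (-0.09, adjusted p = 0.17). It still called ribosomal proteins (-0.19, adjusted p = 9.19e-11), respiratory chain genes (-0.28, adjusted p = 1.48e-08), ribosome biogenesis genes (-0.20, adjusted p = 2.81e-06) and glycolysis genes (-0.22, adjusted p = 0.0117). With library totals the medians were -0.11 for ribosomal proteins, -0.19 for respiratory chain genes, -0.12 for ribosome biogenesis genes, -0.13 for glycolysis genes and -0.03 for SAGA genes, and that of core histones came to 0. With this scaling rps1002 stood at -0.56, rip1 at -0.53 and eno101 at -0.28. Without replicate 2 of untreated WT the median of ribosomal proteins was -0.26.

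Among 20 core stress genes tested, 6 were higher, 1 was lower and 13 did not pass (7 higher and 1 lower adjusted over the list alone), with lsd90 (1.52 ± 0.32) and tms1 (1.24 ± 0.20). Their median was 0.36 (adjusted p = 0.00947, and adjusted p = 0.574 with an estimated correlation). The call was lost without replicate 1 of untreated WT (median 0.15). The median was 0.62 without replicate 2 of untreated WT, 0.23 without replicate 2 of untreated ubp8, 0.66 with library totals and 0.57 in a fit of coding genes alone. Of 16 mating and nitrogen starvation genes tested, 7 were higher, 1 was lower and 8 did not pass (8 higher and 1 lower adjusted over the list alone), with mei2, a driver of meiosis, at 1.35 ± 0.18. The median was 0.44 (adjusted p = 0.00316, and adjusted p = 0.428 with an estimated correlation). With library totals the median was 0.73. Of 5 M-cell mating-type markers tested, 3 were higher and 2 did not pass (4 higher adjusted over the list alone). Their median was 1.22 (adjusted p = 0.0502). Strain background markers are genes often used as auxotrophic markers: of 7 members tested, 5 were lower and 2 did not pass (6 lower adjusted over the list alone), with lys1 at -0.55 ± 0.10. The median was -0.42 (adjusted p = 0.00947, and adjusted p = 0.428 with an estimated correlation). This call was lost without replicate 2 of untreated ubp8 (median -0.29) and against coding genes alone (-0.22, adjusted p = 0.108). With library totals the median was -0.14, and lys1 stood at -0.26. Pseudogenes were higher (11 of 22, adjusted p = 0.000465, and adjusted p = 0.0218 with an estimated correlation).

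In this test 1233 genes were higher and 1947 lower, of which 756 and 34 by at least 2-fold. The split turned with scaling: scaled by library totals alone, the split was 2216 higher and 286 lower, with the median of all genes shifted by 0.29. In a fit of coding genes alone it was 641 higher and 561 lower, with the coding genes' median shifted by 0.204, and with a mean of at least 50 counts 1090 higher and 759 lower. The number of called genes fell from 3180 to 1188 without replicate 2 of untreated WT and to 1361 without replicate 2 of untreated ubp8.

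**Figure D3:**
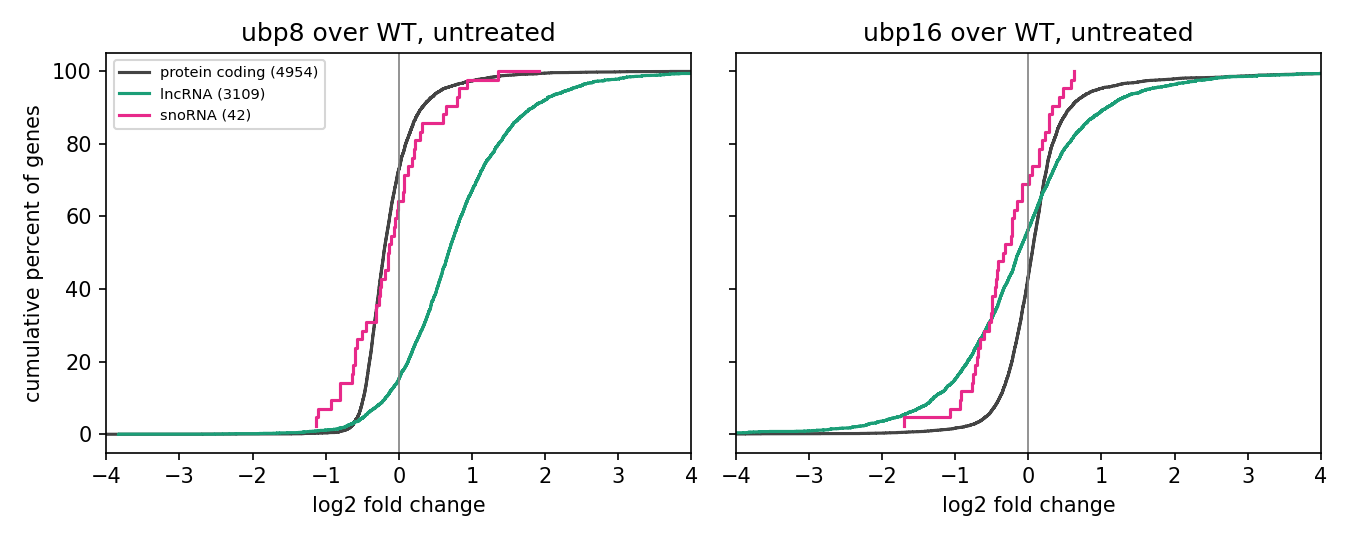
Cumulative percent of tested coding genes, long non-coding RNAs and small nucleolar RNAs against the log2 fold change over WT in untreated cells, for ubp8 (left) and ubp16 (right). In ubp8 the long non-coding RNAs had a median of 0.679 and the coding genes one of -0.206, a value that moves with the scaling of the libraries (by 0.204 in a fit of coding genes alone and by 0.29 over all genes with library totals).

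Untreated ubp16 cells differed from untreated WT by high levels of stress, glucose-repressed and mating genes. High levels were found for mug14 (6.66 ± 0.16), lsd90 (6.56 ± 0.36), ddr48 (6.03 ± 0.35), fbp1 (5.92 ± 0.23) and eno102 (5.28 ± 0.26), of which fbp1 encodes the gluconeogenic fructose bisphosphatase. Low levels were found for mal1 (-3.88 ± 0.21), met17 (-2.85 ± 0.19), aes1 (-2.50 ± 0.31), nrg1 (-2.31 ± 0.24), vht1 (-1.98 ± 0.22) and urg2 (-1.96 ± 0.19); mal1 encodes maltase and met17 homocysteine synthase. Of 20 core stress genes tested, 15 were higher and 5 did not pass (15 higher and 1 lower adjusted over the list alone), with tms1 (3.36 ± 0.19) and zym1 (3.16 ± 0.30), while pyp2 stood at -0.05 ± 0.23, adjusted p = 0.907. Their median was 1.60 (adjusted p = 9.88e-21, and adjusted p = 0.107 with an estimated correlation). Of 10 glucose-repressed genes and hexose transporters tested, 6 were higher, 1 was lower and 3 did not pass (7 higher and 1 lower adjusted over the list alone): gld1 (3.87 ± 0.50), ght5 (3.76 ± 0.13) and ght4 (3.74 ± 0.18) were higher and ght8 (-1.43 ± 0.10) was lower. The median was 3.13 (adjusted p = 4.3e-15, and adjusted p = 0.0685 with an estimated correlation). Among 16 mating and nitrogen starvation genes tested, 12 were higher and 4 did not pass (13 higher adjusted over the list alone), with mei2 (4.36 ± 0.17), mam2 (3.45 ± 0.37) and ste11 (2.31 ± 0.16). Their median was 1.46 (adjusted p = 6.83e-18, and adjusted p = 0.0128 with an estimated correlation). The M-cell mating-type markers went with this group: of 5 members tested, 4 were higher and 1 did not pass (4 higher adjusted over the list alone), with mam1 at 1.20 ± 0.13. The median was 2.11 (adjusted p = 1.39e-06, and adjusted p = 0.107 with an estimated correlation). Of 3 P-cell markers tested, 1 was lower and 2 did not pass (1 lower adjusted over the list alone), namely mfs1 (-0.89 ± 0.11). Their median was -0.89 (adjusted p = 0.183).

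Glycolysis genes were lower in untreated ubp16 cells: of 12 members tested, 2 were higher and 10 were lower (2 higher and 10 lower adjusted over the list alone), with eno101 (-1.75 ± 0.11), fba1 (-1.63 ± 0.13) and tdh1 (-1.51 ± 0.12) lower and hxk1 (0.63 ± 0.09) higher. The median was -0.88 (adjusted p = 1.57e-11, and adjusted p = 0.234 with an estimated correlation). Of 9 iron uptake genes tested, 8 were higher and 1 did not pass (9 higher adjusted over the list alone), with str1 at 1.35 ± 0.18. Their median was 1.10 (adjusted p = 0.000497, and adjusted p = 0.36 with an estimated correlation). Of 16 chaperones tested, 10 were lower and 6 did not pass (13 lower adjusted over the list alone), with ssa1 at -1.12 ± 0.22. The median was -0.43 (adjusted p = 0.000121, and adjusted p = 0.382 with an estimated correlation). Of 139 cytosolic ribosomal proteins tested, 49 were lower and 90 did not pass (54 lower adjusted over the list alone), with rps2202 (-1.72 ± 0.12) and rpl1602 (-1.48 ± 0.09). Their median was -0.27 (adjusted p = 1.54e-11, and adjusted p = 0.561 with an estimated correlation). Pap1 targets went both ways: of 12 members tested, 5 were higher, 3 were lower and 4 did not pass (5 higher and 4 lower adjusted over the list alone), with gst3 (1.96 ± 0.16) higher and bfr1 (-1.15 ± 0.13) and tpx1 (-0.86 ± 0.15) lower. The median was 0.06 (adjusted p = 0.185). Of 10 sulfur assimilation genes tested, 5 were lower and 5 did not pass (7 lower adjusted over the list alone), with sua1 at -0.80 ± 0.11. Their median was -0.37 (adjusted p = 0.000641, and adjusted p = 0.382 with an estimated correlation). The median of ribosomal proteins was -0.16 without replicate 2 of untreated WT or with library totals. That of iron uptake genes was 0.59 without replicate 2 of untreated WT and 0.73 without replicate 1 of untreated ubp16, where ssa1 stood at -0.72.

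In this test 1164 genes were higher and 924 lower, of which 375 and 258 by at least 2-fold. With scaling by library totals alone the split was 1643 higher and 666 lower, with the median of all genes shifted by 0.107. Without replicate 2 of untreated WT the number of called genes fell from 2088 to 1364. The 20 core stress and glucose-repressed genes that were higher were also higher in replicate 2 than in replicate 1 of untreated ubp16, by a median of 0.69, against 0.29 for the same genes in untreated WT.

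The next comparison set treated ubp8 cells against treated WT. Well above WT stood mel1 (3.55 ± 0.27), eno102 (3.55 ± 0.19), cmt2 (3.31 ± 0.15), spn5 (3.19 ± 0.29) and pcm2 (2.76 ± 0.24). Well below WT, besides ubp8, stood bsu1 (-1.91 ± 0.11), zpr1 (-1.85 ± 0.10), hsp16 (-1.66 ± 0.26), inv1 (-1.54 ± 0.13) and met17 (-1.46 ± 0.17). Among 12 Pap1 targets tested, 10 were higher and 2 did not pass (10 higher adjusted over the list alone): caf5 (2.26 ± 0.18), gst2 (1.94 ± 0.17) and trr1 (1.49 ± 0.17) were higher. The median was 0.67 (adjusted p = 4.85e-08, and adjusted p = 0.349 with an estimated correlation). Of 16 chaperones tested, 12 were lower and 4 did not pass (15 lower adjusted over the list alone), with hsp104 (-1.20 ± 0.19), mas5 (-0.96 ± 0.10) and hsp78 (-0.94 ± 0.12). Their median was -0.55 (adjusted p = 2.35e-08, and adjusted p = 0.478 with an estimated correlation). Of 9 MBF genes tested, 6 were higher and 3 did not pass (6 higher adjusted over the list alone), with cdc18 at 1.25 ± 0.15. The median was 0.53 (adjusted p = 0.00178, and adjusted p = 0.58 with an estimated correlation). Of 20 core stress genes tested, 5 were higher, 2 were lower and 13 did not pass (5 higher and 2 lower adjusted over the list alone, adjusted p = 0.136), with zym1 at 1.42 ± 0.24. Of 139 cytosolic ribosomal proteins tested, 1 was higher, 99 were lower and 39 did not pass (1 higher and 110 lower adjusted over the list alone). Their median was -0.40 (adjusted p = 5.19e-21, and adjusted p = 0.58 with an estimated correlation). Of 30 respiratory chain genes tested, 19 were lower and 11 did not pass (23 lower adjusted over the list alone), with cox5 at -0.77 ± 0.11. The median was -0.43 (adjusted p = 8.56e-09, and adjusted p = 0.58 with an estimated correlation). With library totals the medians were -0.24 for ribosomal proteins and -0.27 for respiratory chain genes, and without replicate 1 of treated ubp8 that of the Pap1 targets was 0.44. Among ubiquitin-specific proteases ubp11 was lower (-1.36 ± 0.12) and ubp9 higher (0.41 ± 0.09). Small nucleolar RNAs were lower as a class, with 21 of 42 called and a median of -1.339 (adjusted p = 2.57e-15, and adjusted p = 0.0089 with an estimated correlation).

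In this test 1356 genes were higher and 1281 lower, of which 467 and 243 by at least 2-fold. Library totals alone gave 2128 higher and 769 lower, with the median of all genes shifted by 0.158. Without replicate 1 of treated ubp8 the number of called genes fell from 2637 to 1649.

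After peroxide, ubp16 cells stood far above WT in Pap1 targets: of 12 members tested, 12 were higher (12 higher adjusted over the list alone), with caf5 (4.35 ± 0.19), trr1 (3.49 ± 0.18), gst2 (3.21 ± 0.18) and obr1 (2.73 ± 0.18). Their median was 2.13 (adjusted p = 2.86e-16, and adjusted p = 0.0739 with an estimated correlation). Other genes far above WT were hhy1 (7.68 ± 0.32), mel1 (6.24 ± 0.25), urg1 (6.26 ± 0.27), adh8 (5.57 ± 0.18) and ste11 (5.39 ± 0.26). Marked falls were in met17 (-5.15 ± 0.24), ubp11 (-4.28 ± 0.15), aes1 (-3.42 ± 0.24), zpr1 (-3.31 ± 0.11) and hsp16 (-3.07 ± 0.27) and in Tf2-11, a retrotransposon whose near-identical copies make its reads uncertain (-3.61 ± 0.39). Among 9 iron uptake genes tested, 9 were higher (9 higher adjusted over the list alone), with str3, a heme transporter, at 5.18 ± 0.40. The median was 1.11 (adjusted p = 1.12e-05, and adjusted p = 0.209 with an estimated correlation). Of 10 glucose-repressed genes and hexose transporters tested, 6 were higher, 1 was lower and 3 did not pass (6 higher and 1 lower adjusted over the list alone), with ght4 (4.17 ± 0.18) and ght5 (4.16 ± 0.14) higher and ght2 (-1.96 ± 0.15) lower. Their median was 1.92 (adjusted p = 1.72e-05, and adjusted p = 0.209 with an estimated correlation). Of 16 mating and nitrogen starvation genes tested, 13 were higher and 3 did not pass (13 higher adjusted over the list alone). The median was 1.80 (adjusted p = 2.64e-08, and adjusted p = 0.0739 with an estimated correlation). All 5 M-cell mating-type markers tested belong to this list as well. Of these, 4 were higher and 1 did not pass (4 higher adjusted over the list alone). Their median was 2.91 (adjusted p = 0.00141, and adjusted p = 0.209 with an estimated correlation). With no count filter the median of the glucose-repressed genes and hexose transporters was 0.48.

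Of 16 chaperones in treated ubp16 cells tested, 15 were lower and 1 did not pass (15 lower adjusted over the list alone), with hsp78 at -1.56 ± 0.12. The median was -0.73 (adjusted p = 7.29e-06, and adjusted p = 0.286 with an estimated correlation). Of 57 ribosome biogenesis genes tested, 47 were lower and 10 did not pass (47 lower adjusted over the list alone). Their median was -0.64 (adjusted p = 3.19e-13, and adjusted p = 0.209 with an estimated correlation). Among 139 cytosolic ribosomal proteins tested, 120 were lower and 19 did not pass (1 higher and 128 lower adjusted over the list alone). The median was -0.56 (adjusted p = 1.2e-12, and adjusted p = 0.598 with an estimated correlation). Of 10 sulfur assimilation genes tested, 8 were lower and 2 did not pass (8 lower adjusted over the list alone), with met10 at -1.42 ± 0.11 and met14 at -1.38 ± 0.10. Their median was -0.64 (adjusted p = 0.00169, and adjusted p = 0.409 with an estimated correlation). Of 7 strain background markers tested, 6 were lower and 1 did not pass (6 lower adjusted over the list alone), with lys1 (-1.32 ± 0.10) and ura4 (-1.27 ± 0.10). The median was -1.16 (adjusted p = 1.9e-05, and adjusted p = 0.234 with an estimated correlation). Among 20 core stress genes tested, 7 were higher, 2 were lower and 11 did not pass (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.262), with fbp1 (4.45 ± 0.22) higher and pyp2 (-2.19 ± 0.19) lower. In this test 2344 genes were higher and 2161 lower, of which 929 and 1017 by at least 2-fold.

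The next question was whether the response itself differed from that of WT, tested as an interaction. In ubp8 the response of urg1 differed from that of WT by 3.51 ± 0.33, of urg2 by 3.02 ± 0.27 and of uck2 by 2.86 ± 0.18. From lower untreated levels than in WT, urg1 (-1.17 ± 0.22) and urg2 (-1.06 ± 0.18) fell less in ubp8. Other positive differences were in hhy1 (3.14 ± 0.57), msa1 (2.74 ± 0.33), isp7 (2.29 ± 0.17) and uro1 (2.20 ± 0.31). Negative differences were found for mug45 (-1.99 ± 0.38), bsu1 (-1.97 ± 0.16), inv1 (-1.85 ± 0.27) and hsp16 (-1.79 ± 0.37) and in dad1 (-1.71 ± 0.30) and pbi2 (-1.59 ± 0.33). Of 12 Pap1 targets tested, 7 had a higher response and 5 did not pass (7 higher adjusted over the list alone): caf5 (2.19 ± 0.25), trr1 (1.87 ± 0.24), gst2 (1.86 ± 0.24) and bfr1 (1.62 ± 0.17), while gst3 stood at 0.39 ± 0.21, adjusted p = 0.223. Their median was 0.78 (adjusted p = 8.32e-08, and adjusted p = 0.565 with an estimated correlation). Among 16 chaperones tested, 8 had a lower response and 8 did not pass (12 lower adjusted over the list alone), with hsp78 at -0.75 ± 0.17. The median was -0.51 (adjusted p = 1.4e-05, and adjusted p = 0.565 with an estimated correlation). Of 19 SAGA genes tested, 8 had a higher response and 11 did not pass (11 higher adjusted over the list alone), with spt8 at 0.83 ± 0.16. Their median was 0.36 (adjusted p = 0.000849, and adjusted p = 0.565 with an estimated correlation). The SAGA median was 0.22 against coding genes alone (adjusted p = 0.0386) and without replicate 1 of treated WT, 0.21 without replicate 1 of treated ubp8 and 0.23 with library totals. Of 9 MBF genes tested, 5 had a higher response and 4 did not pass (6 higher adjusted over the list alone). The median was 0.70 (adjusted p = 7.41e-05, and adjusted p = 0.565 with an estimated correlation). Without replicate 1 of treated WT the MBF median was 0.41. Of core stress genes 1 of 20 passed, hsp16 (1 adjusted over the list alone, adjusted p = 0.603). Among the proteases ubp11 had a weaker response (-1.26 ± 0.18). Small nucleolar RNAs had a lower response, with a median of -0.954 (adjusted p = 2.46e-12, and adjusted p = 0.00809 with an estimated correlation), and so did long non-coding RNAs, with a median of -0.453 (adjusted p = 7.93e-18, and adjusted p = 0.00727 with an estimated correlation).

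In this interaction test 856 genes were higher and 518 lower, of which 118 and 364 by at least 2-fold. Library totals alone gave 405 higher and 572 lower, with the median of all genes shifted by -0.132. In a fit of coding genes alone the coding median shifted by -0.144 and 740 genes were called in place of 1374 (1107 with the scaling of all genes). With a mean of at least 50 counts 487 genes were higher and 534 lower. Leaving out 1 library lowered the count to 414 without replicate 1 of treated WT or of treated ubp8, 568 without replicate 2 of untreated WT, 595 without replicate 2 of untreated ubp8, 878 without replicate 2 of treated WT and 908 without replicate 2 of treated ubp8.

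In ubp16 the response differed from WT in opposite directions for Pap1 targets and core stress genes. Of 12 Pap1 targets tested, 10 had a higher response, 1 a lower one and 1 did not pass (10 higher and 1 lower adjusted over the list alone): caf5 (4.33 ± 0.26), trr1 (4.01 ± 0.24), obr1 (3.13 ± 0.25) and bfr1 (3.05 ± 0.18) were higher and gst3 (-1.49 ± 0.21) was lower. Their median was 2.11 (adjusted p = 7.85e-19, and adjusted p = 0.0785 with an estimated correlation). Of 20 core stress genes tested, 15 had a lower response and 5 did not pass (16 lower adjusted over the list alone), with lsd90 (-5.10 ± 0.42), ish1 (-2.64 ± 0.28), hsp16 (-2.36 ± 0.38) and gpx1 (-2.23 ± 0.29). The median was -1.45 (adjusted p = 1.03e-08, and adjusted p = 0.744 with an estimated correlation). As a list these genes already stood above WT in untreated ubp16 cells (median 1.60). In treated cells the list was not called different from WT (median 0.18, adjusted p = 0.262). Peroxide raised urg1 in ubp16 (3.38 ± 0.23), where it fell in WT, and the responses differed by 8.05 ± 0.35 for urg1, 6.97 ± 0.28 for urg2 and 5.77 ± 0.18 for uck2. Other positive differences were in hhy1 (4.98 ± 0.57), osr1 (4.93 ± 0.29), adh8 (4.78 ± 0.24) and urg3 (4.75 ± 0.19), and negative ones in ddr48 (-5.43 ± 0.43), wwm3 (-5.21 ± 0.45), ubp11 (-4.18 ± 0.21) and hsp3101 (-3.60 ± 0.31). Of 9 iron uptake genes tested, 6 had a higher response and 3 did not pass (6 higher adjusted over the list alone), with str3 at 4.08 ± 0.53. Their median was 0.81 (adjusted p = 0.0137, and adjusted p = 0.744 with an estimated correlation). The call was lost without replicate 1 of untreated WT (median 0.78) and against coding genes alone (0.81, adjusted p = 0.0756). In this interaction test 1065 genes were higher and 1175 lower, of which 430 and 532 by at least 2-fold.

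**Figure D4:**
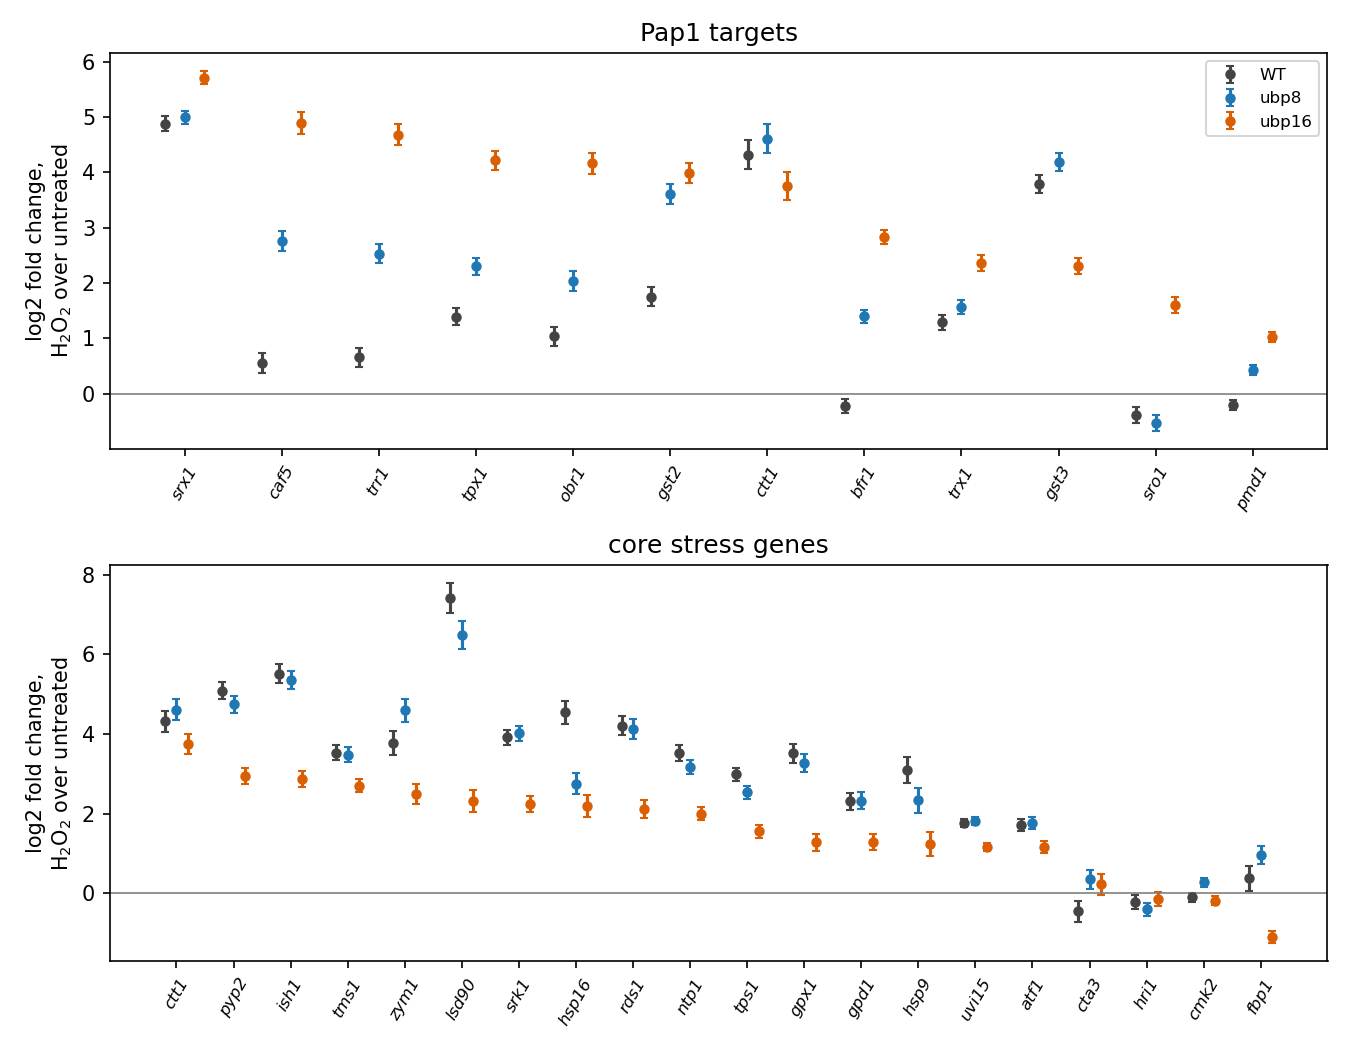
Log2 fold change of treated over untreated cells in WT, ubp8 and ubp16 for each Pap1 target and core stress gene, with bars of 1 SE from 2 libraries per group. The median of the Pap1 targets is 1.16 in WT, 2.42 in ubp8 and 3.87 in ubp16, and that of the core stress genes 3.51, 2.95 and 1.78.

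**Figure D5:**
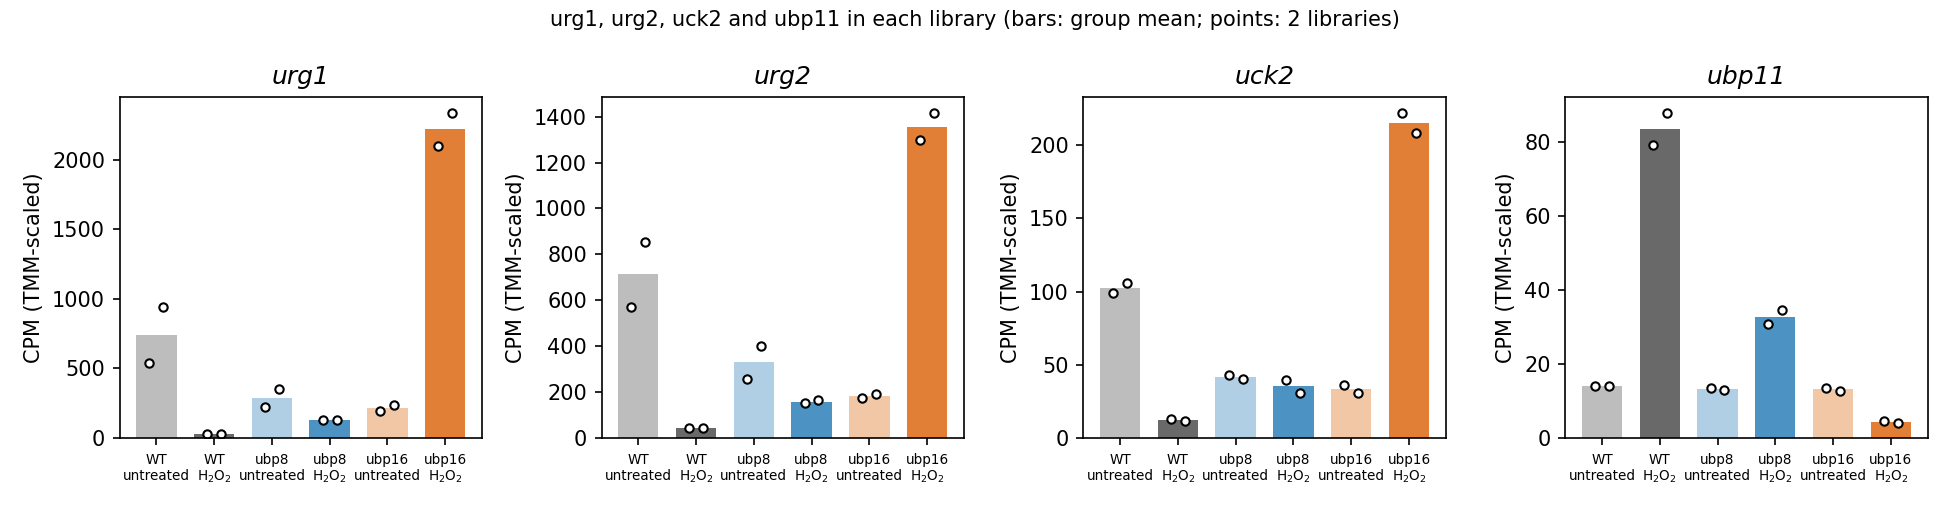
CPM of urg1, urg2, uck2 and ubp11 in each library, with bars for group means and points for the 2 libraries. The response of urg1 differed from that of WT by 3.51 in ubp8 and 8.05 in ubp16 (log2).

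Genes that respond to peroxide were followed as sets chosen in the strain left out of each contrast. The 917 genes induced at least 2-fold in ubp16 had a median of 0.37 in untreated ubp8 over WT (adjusted p = 2.76e-08, and adjusted p = 0.114 with an estimated correlation). It was 0.76 with library totals and 0.66 for genes induced at least 4-fold. In treated cells their median was 0.29 (adjusted p = 2.53e-06, and adjusted p = 0.0957 with an estimated correlation). Here library totals gave 0.52 and the 4-fold set 0.69. Of the 917 genes 403 were long non-coding RNAs, a class with medians of 0.679 untreated and 0.227 treated, which can raise both medians. The 790 repressed genes stood at -0.21 in treated ubp8 over WT (adjusted p = 2.53e-06, and adjusted p = 0.0192 with an estimated correlation), a median that turned to 0.01 with library totals as scaling. The 859 genes induced in ubp8 had a median of 0.47 in untreated ubp16 over WT (adjusted p = 2.23e-24, and adjusted p = 0.0594 with an estimated correlation). Of these, 409 were called higher and 45 lower. The median was 0.75 with library totals, 1.25 for the 4-fold set and 1.60 for the 20 core stress genes. Their response in ubp16 was below that of WT by a median of -0.41 (adjusted p = 4.89e-06, and adjusted p = 0.499 with an estimated correlation). This median was -0.25 without replicate 2 of untreated ubp16, -0.65 with library totals, -0.94 for the 4-fold set and -1.45 for the 20 core stress genes.

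The differences of both mutants from WT overlapped. Untreated, 292 genes were called higher in both, where independent lists of those sizes would share 175.8, and 511 lower in both, where 220.3 would be shared. Opposite calls were made for 181 genes. These counts depend on scaling: with library totals, tried after the values were seen, 675 genes were higher and 116 lower in both, and untreated ubp8 had 286 lower genes in all. After peroxide, 1006 genes were called higher in both, where independent lists of those sizes would share 389.2, and 1009 lower in both, where 339 would be shared, and 72 genes were called in opposite directions. For the interactions, 490 genes were called higher in both, where independent lists of those sizes would share 111.6, and 295 lower in both, where 74.5 would be shared, with 9 opposite calls. With library totals 1501 genes were higher and 681 lower in both after peroxide, and the balance of the interactions turned, to 279 with a higher and 367 with a lower response in both. Both contrasts of each pair use the same WT libraries, of which 2 per group are too few to split between them. In 20 simulations with no effect, shared WT libraries gave a mean covariance of 0.109 untreated, 0.112 treated and 0.219 for the interactions, against observed values of 0.249, 0.692 and 0.692. The simulated correlations were 0.563, 0.534 and 0.547, against observed 0.337, 0.615 and 0.627, across genes that are not independent replicates. Part of the overlap can come from the shared WT libraries.

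The last comparisons set ubp16 against ubp8, which share no library with each other. Untreated, ubp16 stood far above ubp8 in fbp1 (5.34 ± 0.21), isp3 (5.17 ± 0.31), lsd90 (5.03 ± 0.32), ddr48 (4.58 ± 0.32) and ght5 (4.48 ± 0.14). It stood far below ubp8 in aes1 (-4.63 ± 0.28), nrg1 (-4.40 ± 0.21), mal1 (-3.56 ± 0.21) and met17 (-2.19 ± 0.18). Among 30 respiratory chain genes tested, 29 were higher and 1 did not pass (29 higher adjusted over the list alone), with rip1 (1.10 ± 0.11) and cox13 (1.05 ± 0.10). The median was 0.73 (adjusted p = 4.82e-16, and adjusted p = 0.352 with an estimated correlation). Long non-coding RNAs were lower in ubp16 than in ubp8, with a median of -0.827 (adjusted p = 4.3e-35, and adjusted p = 0.000736 with an estimated correlation). In this test 2241 genes were higher and 1476 lower, of which 253 and 1028 by at least 2-fold. Library totals alone gave 1160 higher and 1956 lower, with the median of all genes shifted by -0.183. In a fit of coding genes alone the coding median shifted by -0.228.

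After peroxide, ubp16 stood above ubp8 in isp4 (4.84 ± 0.35), ght5 (4.64 ± 0.14), shu1 (4.58 ± 0.35), osr1 (4.21 ± 0.17) and urg1 (4.11 ± 0.24), and below it in aes1 (-4.11 ± 0.24), met17 (-3.69 ± 0.24), adg1 (-3.45 ± 0.29) and ubp11 (-2.92 ± 0.15). Among 12 Pap1 targets tested, 11 were higher and 1 did not pass (11 higher adjusted over the list alone), with sro1 (2.76 ± 0.15), obr1 (2.18 ± 0.18) and caf5 (2.09 ± 0.17). Their median was 1.23 (adjusted p = 1.2e-13, and adjusted p = 0.0605 with an estimated correlation). In this test 1824 genes were higher and 1736 lower, of which 446 and 805 by at least 2-fold. Library totals alone gave 1320 higher and 2196 lower, with the median of all genes shifted by -0.112.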

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

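Tests of genomic DNA, strand and depth were chosen before the results they measure were seen, all others after. Intervals span genes and omit spread between libraries.

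The response to peroxide differed between ubp8 and WT in the interaction test for 1374 genes. The same test set apart these lists and classes, with median log2 differences of the response from that of WT: Pap1 targets 0.78, chaperones -0.51, SAGA subunit genes 0.36, MBF cell cycle genes 0.70, peroxide-repressed set -0.08, long non-coding RNAs -0.45 and small nucleolar RNAs -0.95. The repressed set was not called with library totals (-0.20, adjusted p = 0.0633) or without replicate 1 of untreated WT (-0.06) or of untreated ubp8 (-0.05). With an estimated correlation the Pap1 targets, chaperones, SAGA and MBF genes (adjusted p = 0.565 each) and the repressed set (adjusted p = 0.169) were not called, while long non-coding RNAs (adjusted p = 0.00727) and small nucleolar RNAs (adjusted p = 0.00809) were. The repressed set stood at -0.20 without replicate 2 of untreated WT or of treated ubp8, -0.19 without replicate 2 of treated WT, and -0.18 without replicate 1 of treated WT or of treated ubp8. The MBF median was 0.41 without replicate 1 of treated WT, and the SAGA median was 0.22 without that library and 0.21 without replicate 1 of treated ubp8. Single genes set apart by the interaction test had log2 differences of urg1 3.51, hhy1 3.14, urg2 3.02, uck2 2.86, msa1 2.74, isp7 2.29, uro1 2.20, caf5 2.19, trr1 1.87, gst2 1.86, bfr1 1.62, spt8 0.83, hsp78 -0.75, ubp11 -1.26, pbi2 -1.59, dad1 -1.71, hsp16 -1.79, inv1 -1.85, bsu1 -1.97 and mug45 -1.99.

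Between ubp16 and WT the interaction test set apart 2240 genes. Lists and classes that differed had medians of core stress genes -1.45, Pap1 targets 2.11, antioxidant enzymes 0.41, chaperones -0.43, cytosolic ribosomal proteins -0.28, ribosome biogenesis genes -0.39, respiratory chain genes -0.21, iron uptake genes 0.81, MBF cell cycle genes 0.45, strain background markers -0.72, peroxide-induced set -0.41, small nucleolar RNAs -0.67 and pseudogenes 0.81. With an estimated correlation none of these was called: adjusted p = 0.0785 for Pap1 targets, 0.744 for core stress, antioxidant, ribosome biogenesis and iron uptake genes and strain markers, 0.838 for chaperones, ribosomal proteins, respiratory chain and MBF genes, 0.499 for the induced set and 0.0736 for small nucleolar RNAs and pseudogenes. Against coding genes alone the antioxidant enzymes (0.40) and iron uptake genes (0.81), each with adjusted p = 0.0756, and the MBF genes (0.46, adjusted p = 0.113) were not called. With median-of-ratios factors the respiratory chain genes were not called (-0.19, adjusted p = 0.0536). Leaving out 1 library ended 5 of these list calls. Without replicate 1 of untreated WT the chaperones (-0.38), respiratory chain genes (-0.17) and iron uptake genes (0.78) were not called. Without replicate 2 of untreated WT the antioxidant enzymes (0.31) and MBF cell cycle genes (0.36) were not called. Without replicate 1 of treated WT the antioxidant enzymes (0.43) and without replicate 2 the respiratory chain genes (-0.16) were not called. Without replicate 1 of untreated ubp16 this held for antioxidant enzymes (0.23) and MBF genes (0.21). Without replicate 2 it held for chaperones (-0.35) and respiratory chain genes (-0.09). Without replicate 1 of treated ubp16 it held for respiratory chain genes (-0.14), and without replicate 2 for MBF genes (0.40). The MBF median was 0.85 and that of the induced set -0.25 without replicate 2 of untreated ubp16, and that of ribosomal proteins was -0.18 without replicate 1 of untreated WT. Single genes set apart by the interaction test had log2 differences of urg1 8.05, urg2 6.97, uck2 5.77, hhy1 4.98, osr1 4.93, adh8 4.78, urg3 4.75, caf5 4.33, str3 4.08, trr1 4.01, obr1 3.13, bfr1 3.05, gst3 -1.49, gpx1 -2.23, hsp16 -2.36, ish1 -2.64, hsp3101 -3.60, ubp11 -4.18, lsd90 -5.10, wwm3 -5.21 and ddr48 -5.43.

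Long non-coding RNAs were higher in untreated ubp8 than in untreated WT. Genomic DNA alone would raise genes about equally per kb. Of 4 equal groups of these RNAs, the most expressed gained 4.84 times the 0.397 CPM per kb of the least (interval 4.09 to 5.46). Reads assigned to the wrong strand would leave RNAs with no gene opposite unmoved, yet the 189 such RNAs had a median of 0.81 (interval 0.62 to 0.95). With every library thinned to the smallest total 892 were called higher, and the median was at least 0.84 with factors from coding genes or library totals, which argues against depth and scaling. After peroxide the class was not called higher in ubp8 than in WT (median 0.227, adjusted p = 0.0608). A change of RNA synthesis or decay in ubp8, another strain difference or a part from DNA stays open and untested.

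Core stress and glucose-repressed genes were higher in untreated ubp16 than in untreated WT, though with an estimated correlation neither list was called (adjusted p = 0.107 and adjusted p = 0.0685). Treated cells or RNA mixed into these libraries would need genes that peroxide raises, yet 3 of the 6 higher glucose-repressed genes were called lower in treated than in untreated ubp16, and the share of treated RNA implied by core stress genes exceeded that implied by Pap1 targets by 17 points (interval 9.8 to 24). The list medians were at least 1.58 with library totals or median-of-ratios factors. These shifted the median of all genes by only 0.107 and -0.019, so the choice among these factors does not account for the pattern. A difference in growth state between the ubp16 and WT cultures cannot be told apart from the strain, since strain and culture go together and the 20 members that were higher differed by a median of 0.69 even between the 2 untreated ubp16 libraries. An effect of the strain itself stays open and untested.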

How the results depend on the processing

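The alternatives were planned before the data were examined, except 5 that were chosen after seeing the data: list tests against coding genes alone, the overlap of the mutants with library totals, 2 fits of fewer genes with the scaling of all genes, and lists without ubp8 and ubp16. The last kept each of 5 calls and gained 1, proteases in the ubp8 response (adjusted p = 0.0468). The first did not call 13 of 109 lists; the genes they are set against differ. The second had 675 shared higher genes untreated, against 292, 116 lower, against 511, 1501 higher treated, against 1006, 681 lower, against 1009, 279 with a higher response, against 490, and 367 with a lower one, against 295; the scaling itself shifts the calls. With sets of genes changed at least 4-fold, the repressed set in untreated ubp8 over WT turned to 0.20 (adjusted p = 0.0433), and in untreated ubp16 over WT it stood at -0.17 (adjusted p = 0.346); fewer genes were in these sets. With the 20 core stress genes in place of the induced set, treated ubp8 (0.20, adjusted p = 0.0681) and treated ubp16 (0.18, adjusted p = 0.142) were not called; fewer genes were tested. The repressed set was not called in untreated ubp8 with median-of-ratios factors (-0.16, adjusted p = 0.0508) or in the ubp8 interaction with library totals (-0.20, adjusted p = 0.0633). Its median turned to 0.18 in untreated and 0.01 in treated ubp8 with library totals, below that of other genes in each; the cause was not tested. A mean of at least 50 counts gave 1849 called genes for untreated ubp8 against WT and 2326 for untreated ubp16 against ubp8, and coding genes alone gave 1202 and 1710, with 740 for the ubp8 interaction. Scaled like all genes, those subsets gave 2731 and 2969, and 2301, 2497 and 1107, so part of each fall came from testing fewer genes and part from the scaling of the subset. A 2-fold threshold gave 1942, 1826 and 1707 genes for the responses of WT, ubp8 and ubp16, 790 and 633 for untreated and 710 and 1946 for treated ubp8 and ubp16 against WT, 482 and 962 for the interactions, and 1281 and 1251 for untreated and treated ubp16 against ubp8. At that threshold 1096 genes were shared by the responses of WT and ubp8 and 895 by those of WT and ubp16; the threshold itself lowers each count. With an estimated correlation 4 list calls held, and 1 of the response set calls; not called were the induced set in untreated ubp8 (0.37), treated ubp8 (0.29), untreated ubp16 (0.47), treated ubp16 (0.14) and the ubp16 interaction (-0.41), and the repressed set in untreated ubp8 (-0.15), the ubp8 interaction (-0.08) and untreated ubp16 (-0.20). The larger correlation within a set widens its test by construction.

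Leaving out 1 library at a time, with the lone sample of a group assumed to vary like the other groups, gave 1188 to 2580 genes for untreated ubp8 against WT, 1364 to 1811 for untreated ubp16 against WT, 414 to 1364 for the ubp8 interaction and 1649 to 1984 for treated ubp8 against WT. The repressed set in the ubp8 interaction ran from -0.20 to -0.05. Fewer samples were fitted, and beyond that the cause was not tested. With 1 library left out, 461 list tests and 1230 gene values kept direction and side of the threshold, 31 and 5 lost their call and 1 gene value gained it. Under the other alternatives 538 list tests and 1852 gene values were the same, 121 list tests (105 of them with an estimated correlation) and 2 gene values lost their call, and 1 gene value gained it. DESeq2, limma-voom, no filter, median-of-ratios factors and the libraries of a comparison alone left each of the 11 gene counts within 1.5 times the main count. The replicate numbers go together in part: replicate 1 minus replicate 2 correlated between groups with a median of 0.14 (-0.17 to 0.42), and over 0.1 in 8 of 15 pairs. All 6 pairs among the WT and ubp16 groups were over 0.1 (0.139 to 0.423), a hint from the data and not the design, and the libraries, with 2 numbers per group, were not treated as paired. A paired fit with replicate block raised the number of called genes in each of the 11 comparisons, from 4346 to 4472 for the response of WT, 2088 to 2304 for untreated and 4505 to 4663 for treated ubp16 against WT, and 1374 to 1680 and 2240 to 2459 for the interactions of ubp8 and ubp16. List calls rose from 109 to 113, with none lost. Gained were glucose-repressed genes in the response of WT (0.50, adjusted p = 0.0273), M-cell markers in untreated ubp8 against WT (1.18, adjusted p = 0.0372), antioxidant enzymes in treated ubp8 against WT (0.13, adjusted p = 0.0437) and chaperones in treated ubp16 against ubp8 (-0.21, adjusted p = 0.0446). Depth limits genes below about 3 counts per library, or 0.293 CPM at the lowest total.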

Other observations

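Small nucleolar RNAs, which guide the modification and processing of ribosomal RNA, were most abundant in treated WT. They made up 0.1892% and 0.1922% of counts there, 0.0446% and 0.0433% in untreated WT, 0.0601% and 0.0616% in treated ubp8 and 0.0316% and 0.0331% in treated ubp16. Of 42 tested, 22 were higher in treated than in untreated WT, and the responses of both mutants were lower, by medians of -0.95 in ubp8 (adjusted p = 0.00809 with an estimated correlation) and -0.67 in ubp16 (adjusted p = 0.0736 with an estimated correlation). The largest gains, chosen after the values were seen, were in snR30 (1120 CPM, log2 3.22), sno16 (165 CPM, 3.14) and snR95 (118 CPM, 3.15).

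All tests of this pattern were chosen after the result was seen. More RNA without poly(A) in the treated WT libraries would raise ribosomal, transfer and small nuclear RNA too. Their summed share rose by at most 0.19 (log2) against at least 2.08 for small nucleolar RNA. The sum held only 311 to 462 counts per WT library, so it covers little of such RNA and cannot decide. A few RNAs took most of the gain in the summed share, with 80.7% of it in the 3 named above, and may account for that share. They do not account for the number called, since 19 others were higher. With library totals or median-of-ratios factors the median was at least 0.67, which argues against scaling. A change in the tails or the decay of these RNAs in WT stays open and untested.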
